A study of Rattus norvegicus with 10 samples.

How the data were processed

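Gene expression was measured in liver samples of male Wistar rats with Affymetrix Rat 230 2.0 arrays, 1 array per sample and 2 arrays for each of 5 diets. Per the labels' protocols, rats ate standard chow or a diet with 42% of energy from lard, olive oil, coconut fat or fish oil for 12 weeks, livers were frozen after an overnight fast, and total RNA was turned into biotin-labelled cRNA. The deposited values are MAS5 signal intensity on a linear scale, computed by the authors per the submitters' processing notes, which give no software version. The 2% trimmed mean of every array was 100, so no further scaling was applied. Raw scans and detection calls were not used here.

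Of 31099 probe sets, 57 controls were removed. The remaining 31042 were turned into log2(signal + 3.1), where 3.1 is the 10th percentile of all values, and the 40% with the lowest mean over all arrays (a signal of about 17.8) were left out, which removed 12417 and kept 18625. Gene symbols came from the platform annotation and were brought up to date by gene identifier: 20826 probe sets had 1 symbol, 436 several and 9780 none, and 0 symbols changed. A gene was called dim in a diet when both arrays lay at or below 12.8, the highest signal of the bacterial trp control probe sets, a sequence that no protocol step adds; its fold change was then given as a bound.

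One linear model with a mean per diet was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 (5 residual degrees of freedom, 5.96 added by empirical Bayes with an intensity trend). The 8 comparisons were each high-fat diet with chow, the mean of the 4 high-fat diets with chow, fish oil with the mean of the other 3, coconut fat with the mean of lard and olive oil, and olive oil with lard; an F-test asked for any difference. P-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. The comparisons, gene lists and alternatives were written down before the data were examined. Named genes were chosen by a rule among probe sets with 1 regular symbol, taking the probe set with the smallest p per gene. In each comparison of a single diet with chow, and for fish oil against the other 3, up to 12 genes with the highest and 12 with the lowest fold changes were taken among those that passed without overlap of the arrays; in the other comparisons up to 6 and 6. Where fewer than 6 passed, the 6 with the smallest p were given. Each list gave up to 4 members that passed, or otherwise up to 2 with the largest fold change.

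Gene lists were tested with limma's camera at a preset correlation of 0.01 on 10470 genes, each represented by its brightest probe set, with p-values adjusted over the pathway lists and, separately, over the marker lists of each comparison. The 21 pathway lists covered cholesterol and fatty acid synthesis, mitochondrial and peroxisomal fatty acid oxidation, other PPAR-alpha targets, ketogenesis, gluconeogenesis, insulin signalling, bile acids, xenobiotics, antioxidants, acute phase, lipoproteins, retinoids, endoplasmic reticulum stress, oxidative phosphorylation, the circadian clock, immediate early genes, the cell cycle and periportal and pericentral genes; 9 marker lists covered liver cell types, blood cells and adipocytes. Of 479 listed names, 429 were on the array annotation. The lists were also tested with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way and compares them with no other genes. With an estimated correlation, camera's test has the 5 residual degrees of freedom, far fewer than with the preset one. A call lost there may reflect this as well as correlated genes, and does not show that a list is unchanged. The simulation did not run this setting.

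The pipeline was tested on simulated data with the measured means and the variances moderated by empirical Bayes, in which only the fish oil arrays were changed. These variances are drawn toward the intensity trend, so the simulation does not test that trend. For fish oil against chow, 20 of 100 probe sets changed by 1 on the log2 scale and 68 of 100 changed by 2 were recovered, with 5 false calls; for fish oil against the other 3 diets these were 35, 77 and 11. For lard against chow, where nothing was changed, 0 were called by limma. A list of 20 genes raised by 0.5 was found in 50 of 50 draws, and an unchanged list in 2 of 50 (unadjusted p under 0.05). Genes were simulated independently of each other. These draws therefore do not give the rate of false list calls where the genes of a list are correlated.

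Alternatives were quantile normalization, a shift to the same 75th percentile, an offset at the 25th percentile, a floor in place of the offset, no dim filter or 60% left out, no or a robust trend, a threshold of 0.10, a fit of only the diets compared, the replicate number as a block, other ways to represent a gene, and each array left out in turn. One alternative, the median as offset with 60% left out, was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.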

Results

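Liver gene expression was measured on 10 arrays, 2 for each of 5 diets. Male Wistar rats, an outbred laboratory strain, had eaten standard chow or a diet with 42% of its energy as fat for 12 weeks and were fasted overnight before the liver was taken. The fat was lard, olive oil, coconut fat or fish oil (cod liver oil in the series' design text). The series' title poses the question of whether the type of fat matters, so each diet was compared with chow and the high-fat diets were compared with one another. No fat share was given for chow. Comparisons with chow do not separate the type of fat from its amount or from other differences in composition. The deposited table gives 1 MAS5 signal per probe set and array for 31099 probe sets, and every array had a 2% trimmed mean signal of 100. The median signal of an array ranged from 28.7 to 31.9, except on the second lard array, where it was 36.8. That array also had the lowest mean correlation with arrays of other diets (0.927). Of the probe sets, 18625 were bright enough to be tested. Arrays of the same diet correlated across probe sets at r = 0.934 to 0.949, and arrays of different diets at 0.922 to 0.949. With 2 arrays per diet, their number limits the precision. The labels describe each array as a liver sample of a rat but do not say whether RNA was pooled, so p-values measure the spread between these samples. Signals are given as mean ± SD (n = 2 per diet). Fold changes are on the log2(signal + 3.1) scale with their standard error (SE), which understates the change of dim genes.

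With fish oil against chow, 29 probe sets passed limma's test at an adjusted p of 0.05, 13 higher and 16 lower, and 20 of them carry a single gene symbol. At an unadjusted p under 0.05 there were 1421, fewer than with olive oil (1561) or lard (1489). Enzymes of fatty acid metabolism were among the genes that rose. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation, went from 2390 ± 179 with chow to 6880 ± 696 with fish oil (2.88-fold, log2 fold change 1.52, SE 0.16, limma adjusted p = 0.00364). Acot1, a cytosolic acyl-CoA thioesterase, was at or below the background bound of 12.8 on both chow arrays and at 667 ± 456 with fish oil, at least 45.6-fold higher (limma adjusted p = 0.00136). This bound was 26.9 without the first and 77.3 without the second fish oil array. Pex11a, which takes part in peroxisome proliferation, rose 3.31-fold, and Acot2, a mitochondrial acyl-CoA thioesterase, rose 2.79-fold (limma adjusted p = 0.032 for each). The second Pex11a probe set (log2 fold change 1.85) and the other 2 Acot2 probe sets (1.23 and 1.47) did not pass. Aldh1a1, which oxidises retinaldehyde to retinoic acid, rose 9.68-fold from 373 ± 116 to 3550 ± 186 (limma adjusted p = 0.00136). Hdc, the enzyme that makes histamine from histidine, rose 12.7-fold from 37.3 ± 5.8 to 506 ± 27 (limma adjusted p = 0.00254). Adh1c, an alcohol dehydrogenase, rose 3.13-fold on 1 probe set, while a brighter probe set of the same gene had a log2 fold change of 0.36 that did not pass. Prps2, a phosphoribosyl pyrophosphate synthetase, was at least 5.42-fold higher on 1 probe set, and its other 2 probe sets did not pass.

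Among the genes that fell with fish oil against chow, Apoa4, an apolipoprotein of triglyceride-rich particles, dropped 5.98-fold from 4950 ± 247 to 835 ± 192 (log2 fold change -2.58, SE 0.2, limma adjusted p = 0.000925). Cyp4a8, a fatty acid hydroxylase, fell from 221 ± 3.11 to 10.5 ± 9.4, with 1 of the 2 fish oil arrays under the background bound (limma adjusted p = 0.019). The size of the fall is therefore loose, with log2 fold changes of -5.02 and -3.47 without the first and the second fish oil array and between -5.02 and -2.64 over all settings and arrays left out. Its second probe set, at -2.52, did not pass. Tm7sf2, a sterol reductase of cholesterol synthesis, fell 7.2-fold, and Il1r1, the type 1 receptor for interleukin-1, fell 2.31-fold on 1 probe set, while its other 2 (-0.3 and -0.84) did not pass. Of enzymes of amino acid breakdown, Gpt, alanine aminotransferase, fell 2.39-fold, Aspg, an asparaginase, 2.56-fold, and Dmgdh, dimethylglycine dehydrogenase, 2.07-fold (limma adjusted p between 0.032 and 0.0339). Cd74, the invariant chain of MHC class II, went from 1100 ± 244 to 474 ± 69.6 (2.3-fold lower, limma adjusted p = 0.045). Cyp2d4, Pakap and Ptprs fell 2.31-, 2.2- and 2.62-fold, each on 1 probe set. The other probe sets, 1 of Cyp2d4 (-0.66), 2 of Pakap (-0.91 and -0.36) and 3 of Ptprs (-0.14, -0.29 and -1.07), did not pass. Smim1 was at least 6.59-fold lower, a bound of 11.1 without the first and 3.92 without the second chow array. Hdc, Aldh1a1 and Apoa4 passed under all 10 planned settings and without any 1 array. So did Acot1 under 9, being too dim to be tested with the lowest 60% left out, and the other 16 named genes each lost their call under at least 1 planned setting. The count of 29 fell to 7 without an intensity trend in limma's variance model, to 14 or 10 without the first or the second fish oil array, to 11 without either lard array and to 5 without the second chow array, where olive oil against chow had 23. The balance of 13 higher and 16 lower turned to 7 and 3 without the second fish oil array, 7 and 4 without either lard array, and 24 and 17 without the first and 4 and 1 without the second chow array. With each array shifted to the same 75th percentile, 17 were higher and 14 lower.

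By gene group, camera at its preset correlation called fatty acid oxidation higher and cholesterol synthesis and periportal genes lower with fish oil than with chow, and 0 of these calls held with an estimated correlation. All 17 genes of mitochondrial fatty acid oxidation had fold changes above 0 (median log2 fold change 0.46, limma camera adjusted p = 3.58e-12, adjusted p = 0.083 with an estimated correlation). In limma 0 members passed over all probe sets and 8 when adjusted over the list alone. Acot2 (1.23 on its brightest probe set) and Eci1 (1.12) had the largest values. Of 15 genes of peroxisomal fatty acid oxidation, 12 lay above 0 (median 0.57, limma camera adjusted p = 8.99e-09, adjusted p = 0.066 with an estimated correlation), with 3 past the threshold over all probe sets (Pex11a, Ehhadh and Acot1, whose product is cytosolic rather than peroxisomal) and 4 adjusted over the list alone. The 16 other PPAR-alpha target genes had a median of 0.43 (limma camera adjusted p = 2.37e-06, adjusted p = 0.066 with an estimated correlation), with 6 higher and 1 lower adjusted over the list alone. The lower one was Cyp4a8, and the same list held Cd36, a fatty acid transporter, at a log2 fold change of 2.55 (SE 0.43, limma adjusted p = 0.054), chosen after its values were seen. Both ketogenesis genes tested, Acat1 (1.02) and Bdh1 (0.85), passed adjusted over the list alone and 0 over all probe sets in limma (limma camera adjusted p = 5.08e-05, adjusted p = 0.066 with an estimated correlation). The retinoid list had a median of 0.27 over 14 genes (limma camera adjusted p = 0.00562, adjusted p = 0.085 with an estimated correlation), of which Aldh1a1 passed over all probe sets and 2 passed adjusted over the list alone. It was lost without the second fish oil or the first chow array.

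Cholesterol synthesis and uptake genes fell as a group with fish oil, with 18 of 20 below 0 (median log2 fold change -0.75, limma camera adjusted p = 1.29e-08). The estimated correlation among these genes was 0.68. The call was lost in that test, which has only 5 degrees of freedom (adjusted p = 0.26 with an estimated correlation). Tm7sf2 was the 1 member past the threshold over all probe sets, and 4 passed adjusted over the list alone. Without the second chow array the median was -0.2 and camera's adjusted p was 0.0968. Periportal hepatocyte genes, those most active near the portal vein, had 9 of 10 members below 0 (median -0.71, limma camera adjusted p = 4.45e-07, adjusted p = 0.066 with an estimated correlation), with Sds at -2.25 and Cdh1 at -1.02. In limma 0 members passed over all probe sets, and 7 lower and 1 higher passed adjusted over the list alone. Gluconeogenesis genes had a median of -0.31 (limma camera adjusted p = 0.00141, adjusted p = 0.23 with an estimated correlation), with 0 members past either threshold, and the call was lost without the first fish oil or the second chow array. Xenobiotic genes had a median of 0.19 (limma camera adjusted p = 0.00141, adjusted p = 0.23 with an estimated correlation), with Aldh1a1 past the threshold over all probe sets and 5 higher and 2 lower adjusted over the list alone. Antioxidant and glutathione genes had the same median (limma camera adjusted p = 0.000277, adjusted p = 0.26 with an estimated correlation), with 0 past the threshold over all probe sets in limma and 3 adjusted over the list alone, Mt2A (2.18) and Nqo1 (1.71) among them. This call was lost without the second fish oil array. Markers of Kupffer cells and other macrophages moved with these groups: 10 of 13 were below 0 (median -0.41, limma camera adjusted p = 0.00103, adjusted p = 0.36 with an estimated correlation), Cd74 among them, whereas the 9 hepatocyte markers had a median of 0.01 (limma camera adjusted p = 0.771). The macrophage call was lost without the first fish oil array. The fry test, which asks whether the genes of a list move on balance one way, passed for the mitochondrial, peroxisomal, PPAR-alpha, ketogenesis, retinoid and periportal lists, and for lymphocyte markers (median -0.21), which camera did not call (limma camera adjusted p = 0.182).

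**Figure D1:**
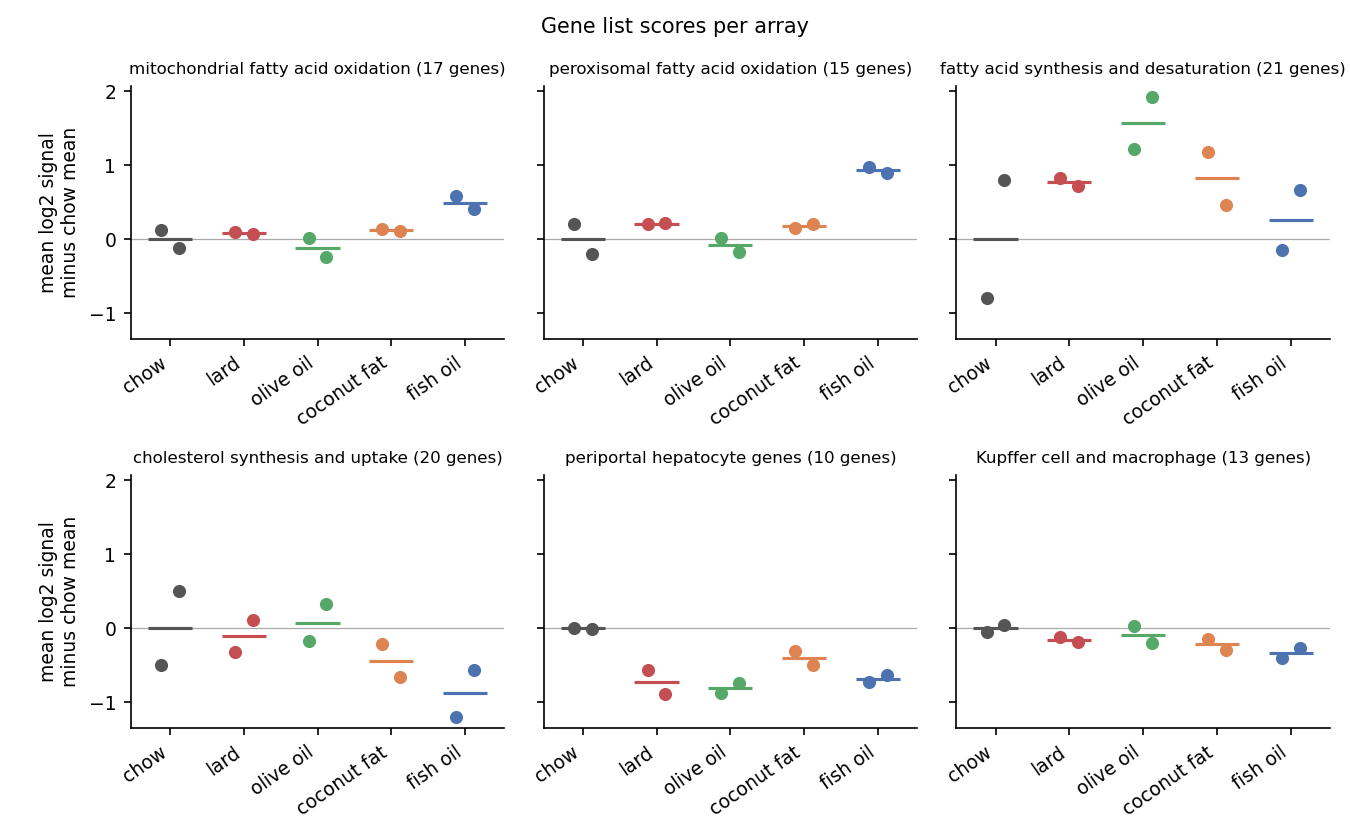
Mean log2 signal of the genes of 6 lists on each of the 10 arrays, minus the mean of the 2 chow arrays; points are arrays and lines are diet means. Both fish oil arrays lie above all others for peroxisomal and mitochondrial fatty acid oxidation, while the 2 chow arrays lie far apart for fatty acid synthesis.

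Set against the mean of the other 3 high-fat diets, fish oil changed 79 probe sets, 35 higher and 44 lower (limma adjusted p under 0.05), of which 60 carry a single symbol. This comparison addresses the source of fat at a similar energy share from fat. It does not separate the type of fat from other components that the sources, cod liver oil among them, may bring. Acot1, Ehhadh and Acot2 were higher with fish oil, the last 2 by 2.8- and 2.83-fold (limma adjusted p = 0.00246, 0.000821 and 0.0113). For Acot1 the log2 fold change was 4.62, but 3.86 without the first and 5.38 without the second fish oil array. Hdc stood 13.1-fold above the other high-fat diets, whose mean signals lay between 33 and 45.6 (limma adjusted p = 0.000556). Mt2A, a metallothionein, reached 3560 ± 1210 against 845 ± 73.3 with lard, 338 ± 227 with olive oil and 609 ± 49.4 with coconut fat (6.42-fold, limma adjusted p = 0.00453), Ugt2b1, a glucuronosyltransferase, was 5.8-fold higher and Gsta3, a glutathione transferase, higher by a log2 fold change of 3.73 (limma adjusted p = 0.0275 and 0.0477). Without the first and the second fish oil array the Gsta3 value was 4.51 and 2.96, and neither passed. Aldh1a1 was 3.78-fold, Aig1 2.92-fold on 1 of 2 probe sets and Ten1 2.73-fold higher. Nat8 was higher by a log2 fold change of 1.95, which was 1.34 without the first fish oil array, where it did not pass, and 2.57 without the second. Cd14, the endotoxin co-receptor, was 3.26-fold higher with fish oil (log2 fold change 1.71, SE 0.2, limma adjusted p = 0.00494). Its signal was 1240 ± 69.3 with fish oil and 1070 ± 39.4 with chow but had diet means between 332 and 501 with the other high-fat diets.

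Apoa4 had the smallest adjusted p of this comparison: 835 ± 192 with fish oil against 4320 ± 1010 with lard, 5510 ± 947 with olive oil and 5720 ± 6.15 with coconut fat (log2 fold change -2.63, SE 0.16, limma adjusted p = 9.18e-05). Cyp4a8 was lower on both its probe sets (limma adjusted p = 0.00382 and 0.0364). The brighter one was near background with fish oil, and its log2 fold change was -4.77 and -3.22 without the first and the second fish oil array and lay between -4.77 and -2.43 over all settings and arrays left out. Inhba, the beta A subunit of activin, fell 2.98-fold from diet means of 636 to 739 to 228 ± 13.1 (limma adjusted p = 0.00254), and Ptprs fell 3.32-fold, although its other probe sets had log2 fold changes of 0.08, -0.81 and -1.24, of which the last passed. Cav2, a caveolin, was 5.02-fold lower, while its 3 other probe sets had log2 fold changes of -0.73 to -1.27 that did not pass. Extl1 was 2.81-fold lower, although its second probe set had a log2 fold change of -0.18. Spin2b was lower by a log2 fold change of -2.4, which was -1.72 without the first fish oil array, where it did not pass, and -3.07 without the second. Cmya5 was lower too, with a fish oil mean of 10.9 ± 5.59 that lay under the background bound of 12.8 and log2 fold changes between -2.61 and -1.73 over the settings and arrays left out. For Smim1, Vxn, Dync2i1 and Agpat3 the fish oil arrays were at or below background, and the signals were at least 6.12-, 3.12-, 2.86- and 2.9-fold lower. The second Vxn probe set (-1) and the other 3 Agpat3 probe sets (-0.83, -0.15 and -0.55) did not pass. Hdc and Apoa4 passed under all 10 planned settings and Acot1 under the 9 that tested it, each also without any 1 array, whereas Gsta3 passed under 4 of 10 settings. The count of 79 fell to 6 without the intensity trend, rose to 120 in a fit of only these 4 diets, and was 44 and 34 without the first and second fish oil arrays, 31 and 44 without the first and second lard arrays and 41 without the first coconut fat array. The balance of 35 higher and 44 lower turned to 17 and 14 without the first and 25 and 19 without the second lard array, 39 and 33 without the first olive oil array, and 22 and 19 without the first and 33 and 28 without the second coconut fat array. A shift to the same 75th percentile gave 44 higher and 35 lower.

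Camera at its preset correlation also called fatty acid oxidation higher with fish oil than with the other high-fat diets, and 0 of the calls of this comparison held with an estimated correlation. All 17 mitochondrial genes were above 0 (median 0.34, limma camera adjusted p = 2.82e-12, adjusted p = 0.14 with an estimated correlation). Acot2 and Cpt2 passed over all probe sets and 12 adjusted over the list alone. Of 15 peroxisomal genes, 13 were above 0 (median 0.42, limma camera adjusted p = 3.78e-10, adjusted p = 0.1 with an estimated correlation), with 3 and 9 past the respective thresholds. Xenobiotic metabolism rose (18 of 20 above 0, median 0.53, limma camera adjusted p = 5.51e-11, adjusted p = 0.1 with an estimated correlation), with Ugt2b1, Aldh1a1 and Gstp1 past the threshold over all probe sets and 12 adjusted over the list alone. Antioxidant and glutathione genes rose (median 0.43, limma camera adjusted p = 1.95e-07, adjusted p = 0.17 with an estimated correlation), led by Mt2A and Gstp1, with 6 adjusted over the list alone. Fatty acid synthesis genes were lower (18 of 21 below 0, median -0.71, limma camera adjusted p = 6.05e-05, adjusted p = 0.41 with an estimated correlation), with Pnpla3 at -2.99 and Fasn at -2.41. The Fasn value was -0.62 without the first and -4.21 without the second fish oil array, and the Pnpla3 value -2.34 without the first and -3.63 without the second coconut fat array. In limma 0 members passed over all probe sets, and 6 lower and 1 higher adjusted over the list alone. Cholesterol synthesis genes were lower (19 of 20 below 0, median -0.73, limma camera adjusted p = 4.75e-07, adjusted p = 0.38 with an estimated correlation), with 5 adjusted over the list alone. Both of these calls were lost without the first fish oil array. Other PPAR-alpha targets (median 0.34, 6 higher and 1 lower adjusted over the list alone, Cyp4a8 again being lower) and ketogenesis genes (0.52) were higher, and gluconeogenesis genes (-0.16) lower (limma camera adjusted p = 0.00158, 0.00718 and 0.0267; adjusted p = 0.17, 0.17 and 0.38 with an estimated correlation). Without the first fish oil array these 3 calls were lost. Pericentral genes (0.48), endoplasmic reticulum stress genes (0.05) and acute phase genes (-0.1, with Il1r1 at -0.87) also passed camera (limma adjusted p = 0.00718, 0.0365 and 0.00718; adjusted p = 0.29, 0.17 and 0.41 with an estimated correlation). With 1 array left out, the stress call was lost without the second lard, the first olive oil, the first coconut fat or the first fish oil array, and the acute phase call without the first olive oil or the first fish oil array. Macrophage markers (median -0.36, limma camera adjusted p = 0.0166), lymphocyte markers (-0.41, 0.0471) and red blood cell markers (-0.61, 0.0471) were lower alongside (adjusted p = 0.35, 0.35 and 0.51 with an estimated correlation). Of the 13 macrophage genes, Cd14 (1.71) and Adgre1 (0.02) lay above 0 and the rest below. The red blood cell list had only 3 genes tested. Fry passed for the mitochondrial, peroxisomal, ketogenesis, xenobiotic, antioxidant and lymphocyte lists. The macrophage call was lost without the first fish oil array, and the lymphocyte and red blood cell calls each in 8 of the 10 fits with 1 array left out.

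**Figure D2:**
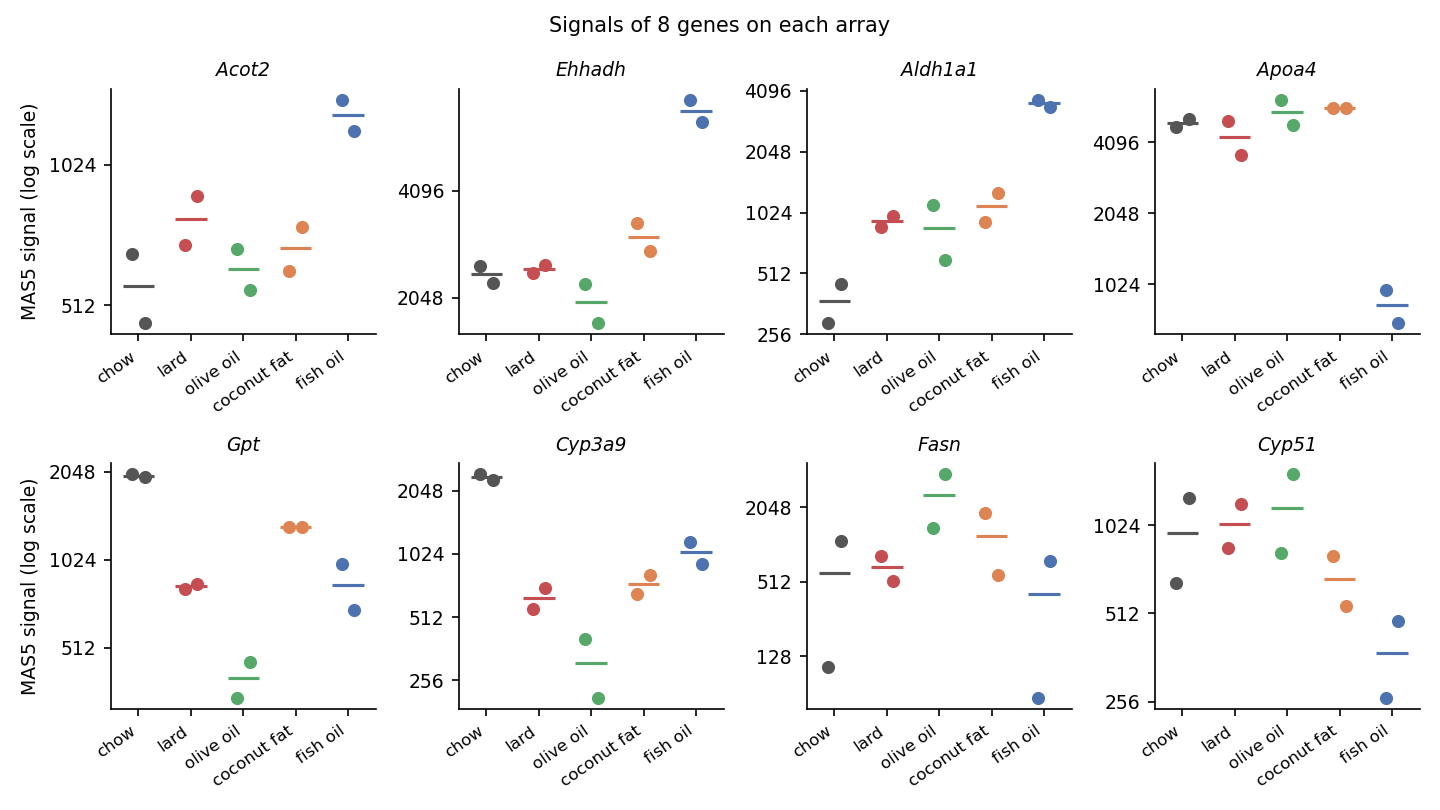
MAS5 signal of 8 genes on each array by diet, on a log scale with a separate range per gene; points are arrays, lines are diet means, and each gene is shown by its brightest probe set. Ehhadh, Acot2 and Aldh1a1 are highest and Apoa4 lowest on both fish oil arrays, Gpt and Cyp3a9 are highest on both chow arrays, and Fasn ranges from 105.8 to 1096.8 between the 2 chow arrays.

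The mean of the 4 high-fat diets differed from chow at 7 probe sets, 3 higher and 4 lower (limma adjusted p under 0.05). Of enzymes of amino acid breakdown, Sds, serine dehydratase, fell 8.35-fold from 785 ± 129 with chow to diet means between 38.2 and 218 with the high-fat diets, Got1, cytosolic aspartate aminotransferase, 2.93-fold and Gpt 2.54-fold (limma adjusted p = 0.0205, 0.0192 and 0.0161). Cyp3a9, a cytochrome P450 of steroid and drug oxidation, went from 2380 ± 103 with chow to diet means between 308 and 1040 (3.88-fold lower, limma adjusted p = 0.0161). Aldh1a1 rose 3.57-fold, Tsc22d1, a leucine zipper regulator, 2.85-fold, and Slpi, a secreted protease inhibitor, was at least 9.1-fold higher than its background level with chow (limma adjusted p = 0.0205, 0.0346 and 0.0455). The second Tsc22d1 probe set had a log2 fold change of 0.33 that did not pass. Periportal genes were lower as a group (9 of 10 below 0, median -0.31, limma camera adjusted p = 8.32e-08, adjusted p = 0.15 with an estimated correlation), with Sds past the threshold over all probe sets and 4 adjusted over the list alone. Retinoid genes (median 0.29), ketogenesis genes (0.55) and other PPAR-alpha targets (0.22) were higher (limma camera adjusted p = 0.00607, 0.00135 and 0.00162; adjusted p = 0.15 for each with an estimated correlation), the first of these not without the first chow array. Mitochondrial (0.17) and peroxisomal oxidation genes (0.09, but -0.02 without the first olive oil array) passed camera as well (limma adjusted p = 0.013 and 0.0405; adjusted p = 0.63 and 0.58 with an estimated correlation). Both calls were lost without the second chow array, and the peroxisomal one also without either fish oil array, among others. The mean log2 signal of the peroxisomal genes minus that of chow was 0.969 and 0.898 on the fish oil arrays. It was -0.171 to 0.221 on the other high-fat arrays, and 0.203 and -0.203 on the chow arrays. For the mitochondrial genes these values were 0.585 and 0.403, -0.248 to 0.143, and 0.122 and -0.122. Fatty acid synthesis genes were higher than with chow (20 of 21 above 0, median 0.64, limma camera adjusted p = 1.88e-09, adjusted p = 0.45 with an estimated correlation), but the median was -0.03 without the first chow array and 1.42 without the second. The 2 chow arrays differed in this group: all 21 genes were higher on the second, by a median of 1.57 on the log2 scale, with Scd at 547.5 and 5610.4 and Thrsp at 508.3 and 4907.8. The 20 cholesterol genes differed the same way by a median of 0.9; with the high-fat diets their median against chow was -0.21 (limma camera adjusted p = 0.00441, adjusted p = 0.67 with an estimated correlation) and 0.16 without the second chow array. The count of 7 was 0 without the trend, 16 with a robust one, 12 with the lowest 60% of probe sets left out, 2 without the second lard array and 11 without the second fish oil array. Without the first chow array limma called 1 higher and 0 lower, 0 of them among the 7, and without the second 9 higher and 0 lower, 1 of them among the 7. The 4 lower calls were lost either way, but their log2 fold changes moved little over the settings and arrays left out: -3.23 to -2.66 for Sds, -2.07 to -1.84 for Cyp3a9, -1.64 to -1.46 for Got1 and -1.41 to -1.28 for Gpt. The values of the 3 higher genes ran from 2.16 to 4.7 for Slpi, 1.52 to 2.16 for Aldh1a1 and 1.26 to 1.76 for Tsc22d1. The size of the Slpi rise is therefore loose. Fry passed for the retinoid and periportal lists. With the 75th percentile shift, 1 was higher and 4 lower.

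**Figure D3:**
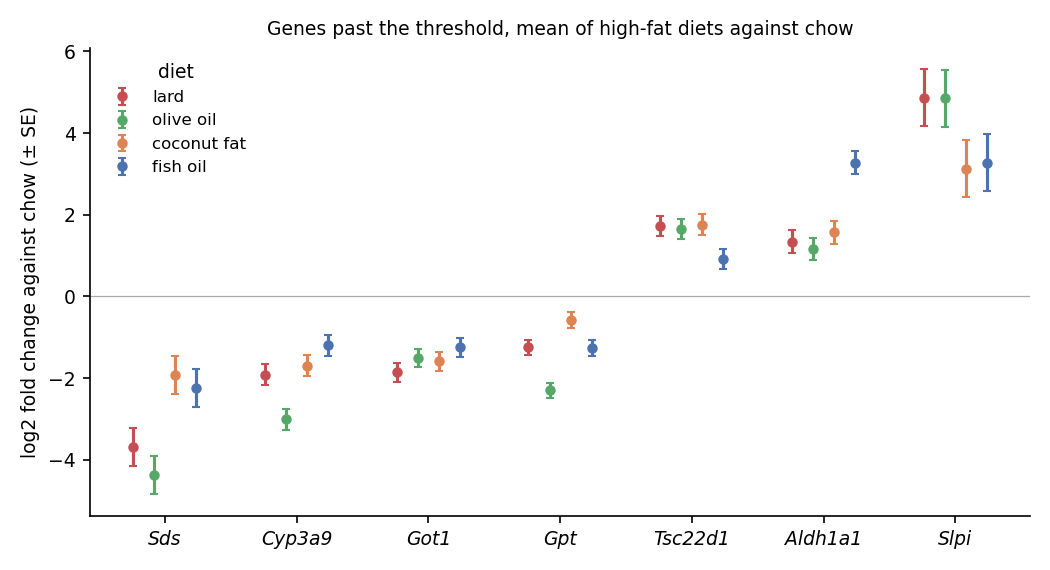
Log2 fold change against chow with its standard error for each high-fat diet, for the 7 genes that passed the threshold in the mean of the high-fat diets. Sds, Cyp3a9, Got1 and Gpt lie below 0 and Tsc22d1, Aldh1a1 and Slpi above 0 with every diet, and Aldh1a1 is highest with fish oil.

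Olive oil against chow gave 5 probe sets, 1 higher and 4 lower (limma adjusted p under 0.05). Gpt fell 4.93-fold to 403 ± 80, Cyp3a9 8.06-fold to 308 ± 136 and Sds to 38.2 ± 24.5 (limma adjusted p = 0.00156, 0.00173 and 0.00843). The Sds log2 fold change was -4.38, with -3.74 (not past the threshold) without the first and -5.03 without the second olive oil array. Plcb3, a phospholipase C, was at least 5.45-fold lower, since both olive oil arrays were at background. Rprm, reprimo, a cell cycle inhibitor, rose 4.74-fold from 43.6 ± 13.2 to 214 ± 12.7 (limma adjusted p = 0.00843). Cd14 had a log2 fold change of -1.74 and missed the threshold (limma adjusted p = 0.0526). Fatty acid synthesis genes were higher as a group (20 of 21 above 0, median 1.45, limma camera adjusted p = 5.53e-15, adjusted p = 0.3 with an estimated correlation), with Pnpla3 at 5.08 and Fasn at 2.73. Without the first and the second chow array these were 4.15 and 6.01 for Pnpla3 and 1.06 and 4.4 for Fasn, and without the first and the second olive oil array 6.02 and 4.15, and 3.45 and 2.01. In limma 0 members passed over all probe sets and 14 adjusted over the list alone. The median was 0.66 without the first chow array and 2.42 without the second. Xenobiotic genes (17 of 20 below 0, median -0.3, limma camera adjusted p = 2.6e-05) and periportal genes (9 of 10 below 0, median -0.21, limma camera adjusted p = 1.17e-05) were lower, each with adjusted p = 0.3 with an estimated correlation; Cyp3a9 and Sds were their members past the threshold over all probe sets. Bile acid genes (median -0.22), antioxidant genes (-0.25) and pericentral genes (-0.26) were lower and acute phase (0.22) and lipoprotein genes (0.17) higher (limma camera adjusted p = 0.0242, 0.0192, 0.0192, 0.00835 and 0.0188; adjusted p = 0.3, 0.44, 0.3, 0.37 and 0.3 with an estimated correlation). Each of these 5 calls was lost without 1 of the 2 olive oil arrays. The log2 ratio of the 3' to the 5' Gapdh probe set, a sign of RNA quality, was 0.14 and 0.25 on the olive oil arrays and -0.06 to 0.07 on the other 8. For Actb it was 1.32 and 1.46 against 1.07 to 1.38, so RNA quality was not separated from the olive oil diet. The count of 5 was 3 without the first chow array, 23 (15 higher and 8 lower) without the second, 19 without the second olive oil array, 11 and 9 without the first and second coconut fat arrays and 10 without either fish oil array. It was 0 without the trend, 15 with a robust one, 11 with no dim filter and 16 with the lowest 60% left out.

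Lard against chow gave 3 probe sets, all lower (limma adjusted p = 0.0464 for each). Sds fell 12.9-fold to 60.8 ± 28.1, Got1 3.64-fold to 371 ± 5.3 and Mettl7b, a methyltransferase-like protein of lipid droplets, 2.57-fold from 1590 ± 233 to 613 ± 39.7. Cyp3a9 (log2 fold change -1.92), Tsc22d1 (1.72) and Slpi, at background with chow and at least 16.7-fold higher with lard, missed the threshold (limma adjusted p = 0.0719, 0.0847 and 0.0847). The second Tsc22d1 probe set had a log2 fold change of 0.8. Periportal genes were lower (9 of 10 below 0, median -0.28, limma camera adjusted p = 3.6e-06, adjusted p = 0.23 with an estimated correlation). Fatty acid synthesis genes had a median of 0.63 (20 of 21 above 0, limma camera adjusted p = 0.000102, adjusted p = 0.55 with an estimated correlation), which was -0.13 without the first chow array. Xenobiotic genes (median -0.3) were lower (limma camera adjusted p = 0.000626, adjusted p = 0.23 with an estimated correlation). This call was lost without the first lard array. Also lower were endoplasmic reticulum stress genes (-0.15), antioxidant genes (-0.19) and oxidative phosphorylation genes (-0.07, but 0.02 after quantile normalization and 0.07 without the second chow array), while other PPAR-alpha targets (0.22) and ketogenesis genes (0.45) were higher (limma camera adjusted p between 0.0232 and 0.0482, adjusted p between 0.23 and 0.8 with an estimated correlation). Each of these 5 calls was lost without at least 1 array. The count of 3 was 0 without the first lard array, 6 without the second and 1, a higher one, without the first chow array, with 0 of the 3 genes among these. Without the second chow array 3 were higher and 1 lower in limma, 1 of them among the 3. It was 0 with quantile normalization or with a floor in place of the offset, 1 without the trend and 8 in a fit of lard and chow alone.

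Coconut fat against chow gave 0 probe sets past limma's adjusted threshold, with 1012 at an unadjusted p under 0.05 where chance gives 931. The 6 genes with the smallest p did not pass. Got1 (-1.59), Wsb1 (-1.7), Cd14 (-1.66) and Cyp3a9 (-1.7) had log2 fold changes below 0, and Tsc22d1 (1.76) and Pyroxd2 (1.99) above 0 (limma adjusted p between 0.141 and 0.168). The second probe sets of Tsc22d1 and Pyroxd2 had log2 fold changes of 0.15 and 1.57. Of the gene groups, fatty acid synthesis had a median of 0.7 (20 of 21 above 0, limma camera adjusted p = 1.23e-06, adjusted p = 0.69 with an estimated correlation) that was 0.01 without the first chow array. Periportal genes had a median of -0.16 (9 of 10 below 0, limma camera adjusted p = 0.00983, adjusted p = 0.47 with an estimated correlation). This call was lost without the second coconut fat or the second chow array. Cholesterol genes (-0.26, but 0.07 without the second chow array) were lower and retinoid (0.24), ketogenesis (0.41), acute phase (0.13), lipoprotein (0.12) and mitochondrial oxidation genes (0.11) higher (limma camera adjusted p = 0.00336 for the first and between 0.0334 and 0.0372 for the others, adjusted p between 0.47 and 0.76 with an estimated correlation). Without the second coconut fat array all 6 of these calls were lost. A fit of these diets alone gave 5 probe sets, and leaving out 1 array gave 3 without the first chow array, 2 without either fish oil or either olive oil array and 1 without the second coconut fat array.

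Among the 3 high-fat diets without fish oil, 0 probe sets passed limma's adjusted threshold, both for coconut fat against the mean of lard and olive oil (1249 at an unadjusted p under 0.05) and for olive oil against lard (1160). Gpt had the smallest p for coconut fat: 1330 ± 0.283 against 830 ± 24.3 with lard and 403 ± 80 with olive oil (2.3-fold, limma adjusted p = 0.234). Dao, D-amino acid oxidase, was at 759 ± 46.5 with coconut fat and 369 ± 98.3 with lard (limma adjusted p = 0.267). Cholesterol synthesis genes had a median of -0.45 with coconut fat (19 of 20 below 0, limma camera adjusted p = 0.00149), and xenobiotic genes one of 0.22 (limma camera adjusted p = 5.75e-05), with adjusted p = 0.63 and 0.51 with an estimated correlation. Both calls were lost without the second coconut fat array. Oxidative phosphorylation genes (0.11), mitochondrial oxidation genes (0.12), periportal genes (0.16) and antioxidant genes (0.08) were higher with coconut fat (limma camera adjusted p = 0.0013, 0.00195, 0.00195 and 0.0307; adjusted p = 0.63, 0.63, 0.51 and 0.63 with an estimated correlation). Each of these calls was lost without at least 1 array. In olive oil against lard, fatty acid synthesis genes were higher (20 of 21 above 0, median 0.64, limma camera adjusted p = 2.38e-06, adjusted p = 0.42 with an estimated correlation), as were endoplasmic reticulum stress genes (11 of 15, median 0.31, limma camera adjusted p = 8.12e-05, adjusted p = 0.1 with an estimated correlation). The first of these was lost without the second olive oil array. Mitochondrial (-0.18) and peroxisomal oxidation genes (-0.26) and pericentral genes (-0.38) were lower and gluconeogenesis (0.25), acute phase (0.16) and lipoprotein genes (0.13) higher with olive oil (limma camera adjusted p between 0.00329 and 0.0236, adjusted p = 0.42 for each with an estimated correlation). Each of these 6 calls was lost without at least 1 array. Plcb3 was at 62.1 ± 5.66 with lard and at background with olive oil, a difference of at least 4.84-fold that did not pass (limma adjusted p = 0.209). Fits of only the diets compared gave 1 and 3 probe sets. 1 array left out gave 1 for coconut fat without the first olive oil array, and 3, 3 and 4 for olive oil without the second lard, the first olive oil and the second olive oil arrays.

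Across all 5 diets, limma's F-test found 26 probe sets that differed between any of them, 20 with a single symbol. The count was 10 and 12 without the first and second fish oil arrays, 13 without the first lard array and 1 without the trend. Of 240 list tests over the 8 comparisons, camera with its preset correlation called 72, and 14 of these also passed fry. With an estimated correlation 0 of the 72 held (lowest adjusted p = 0.066 in limma's camera). That test has only 5 degrees of freedom, so the lost calls do not show that the lists are unchanged.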

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

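Of the patterns below, the test of non-hepatocyte markers was chosen after the result was seen. Macrophage markers were lower with fish oil than with chow (10 of 13 genes below 0, median log2 fold change -0.41, Cd74 at -1.2 but Cd14 at 0.2). Array scaling did not account for this: after quantile or 75th percentile scaling the median was -0.39. A lower share of all non-hepatocyte cells in the fish oil pieces may explain it, and then markers of endothelial and stellate cells should be lower too; their median was -0.09 (19 genes, SE 0.15), above the bound of -0.21 set for this explanation by too little against its spread to decide, so this and a change in macrophages alone cannot be told apart. Fewer macrophages and a lower expression in them were not tested against each other.

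For 16 genes, the fold changes against chow of fish oil and of the other 3 high-fat diets had opposite signs and differed in limma. That test is the comparison of fish oil with the other 3 diets by which the genes were named. It does not test on which side of chow either lies. The signs are those of 1 probe set per gene. Other Acot2 probe sets had 1.23 and 1.48 for fish oil against chow but 0.93 and 1.23 against the other 3 diets. On these the other 3 diets also lay above chow. Likewise, 1 other Ptprs probe set (-0.14 against chow, 0.08 against the other 3 diets) put both below chow, while the rest of Ptprs kept opposite signs. Higher with fish oil were Gsta3 (difference 3.73 on the log2 scale), Hdc (3.72), Mt2A (2.68), Ugt2b1 (2.54), Nat8 (1.95), Cd14 (1.71), Aig1 (1.55), Acot2 (1.5) and Ten1 (1.45). Lower were Apoa4 (-2.63), Cav2 (-2.33), Agpat3 (-2.2), Cmya5 (-2.19), Ptprs (-1.73), Inhba (-1.58) and Extl1 (-1.49). Agpat3, at background on both fish oil arrays, was at least 2.9-fold lower, and Cmya5, with a fish oil mean of 10.9 under the background bound of 12.8, ran from -2.61 to -1.73 over the settings and arrays left out, so the 2 values given for them are loose. With the other diets Acot2 (-0.03), Hdc (-0.05), Apoa4 (0.05), Aig1 (-0.08), Agpat3 (0.13), Gsta3 (-0.18) and Extl1 (0.24) were close to chow, and the opposite sign was not tested for any of the 16. Cd14 was near chow with fish oil (0.2) and below it with the others (-1.5), and Cav2 (-1.26 and 1.07), Inhba (-0.88 and 0.69) and Nat8 (0.63 and -1.32) had values on both sides. The cause was not tested.

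The Bacillus spike-in controls, RNAs added before labelling, were 2.54-fold higher on the first olive oil array than the median of the other 9, while its hybridization controls were 1.22-fold higher. The cause was not tested, and the controls were not used in any comparison.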

How the results depend on the processing

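With 2 arrays per diet, counts moved with the settings, while in both fish oil comparisons Hdc and Apoa4 passed under all 10 planned settings, Acot1 under the 9 that tested it, and all without any 1 array. Of 64 calls of named genes, 57 were lost without an intensity trend, 3 after a 75th percentile shift and between 10 and 36 with 1 array left out (36 without each fish oil array), and 0 reversed in limma where they were tested. The cause was not tested. Without an intensity trend limma called 7 probe sets for fish oil against chow, 6 against the other 3 diets, 1 for lard, 0 for olive oil, 0 for the high-fat mean and 1 in the F-test; with a robust trend it called 15 for olive oil and 16 for the high-fat mean. At a threshold of 0.10 the counts were 62 and 208 for fish oil against chow and the other 3 diets, 7 for lard, 21 for olive oil, 20 for the high-fat mean and 49 in the F-test. Fits of only the diets compared gave 120 for fish oil against the other 3, 8 for lard, 5 for coconut fat, 1 for coconut fat against lard and olive oil and 3 for olive oil against lard. With the lowest 60% left out, olive oil gave 16 and the high-fat mean 12; with the median as offset as well, chosen after the data were seen, 15 and 11; with no dim filter, olive oil gave 11. Lard gave 0 with quantile normalization and 0 with a floor. Of 72 list calls, 0 held with an estimated correlation, a test with 5 degrees of freedom, and fry made 15. Oxidative phosphorylation in lard against chow had a median of 0.02 after quantile normalization. The test of only the diets compared does not apply to the F-test and equals the fit of all arrays for the high-fat mean. The 12417 probe sets with the lowest mean over all arrays were tested only with no dim filter.

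With 1 array left out, the lone array of its diet is assumed to vary like the others. Counts then ranged from 5 (second chow array) to 41 (first chow array) for fish oil against chow, 31 (first lard) to 113 (first chow) against the other 3, 0 (first lard) to 6 (second lard) for lard, 3 (first chow) to 23 (second chow) for olive oil, 0 to 3 (first chow) for coconut fat, 1 (first chow) to 11 (second fish oil) for the high-fat mean, 0 to 1 (first olive oil) for coconut fat against lard and olive oil, 0 to 4 (second olive oil) for olive oil against lard, and 10 (first fish oil) to 36 (first chow) in the F-test. Medians of fatty acid synthesis genes ran from -0.13 to 1.43 for lard, 0.01 to 1.49 for coconut fat and -0.03 to 1.42 for the high-fat mean, without the first and the second chow array. Those of cholesterol genes ran from -0.76 to 0.07 for coconut fat and -0.66 to 0.16 for the high-fat mean. Oxidative phosphorylation with lard ran from -0.23 to 0.07 and peroxisomal oxidation with the high-fat mean from -0.02 to 0.21. Decr1 with coconut fat ran from -0.04 to 0.73, and Lcn2 in olive oil against lard from -0.28 to 1.75.

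The replicate numbers were tested as a pairing. Deviations of arrays with the same number correlated across probe sets at r = -0.033 to 0.076 over 10 pairs of diets, 0 of them over 0.1. The numbers thus showed no pairing over all probe sets, which does not exclude a shared effect on a group of genes. Cholesterol genes had median log2 differences, second minus first array, of 0.49 with lard, 0.56 with olive oil, 0.51 with fish oil and 0.9 with chow, but -0.39 with coconut fat. With a replicate block, limma called 20 probe sets for fish oil against chow, 60 against the other 3 diets and 0 for lard, and camera called 73 lists.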

Other observations

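Of the tests below, those of pericentral genes and of array scaling were chosen after the result was seen, and the amino acid list was written after the leading genes were seen. Some amino acid breakdown genes beyond Sds, Got1 and Gpt also had values below 0 with the high-fat diets against chow. These were Asl (log2 fold change -1.06), Hal (-0.83), Gls2 (-0.8), Aass (-0.73) and Gnmt (-0.66), which did not pass over all probe sets in limma. Of the 43 genes of the list, Sds, Got1 and Gpt included, 29 were below 0 (median -0.2), and 14 lower, these 3 included, and 1 higher, Bckdha (0.44), passed adjusted over the list alone. The medians were -0.24 with lard, -0.29 with olive oil, -0.08 with coconut fat and -0.27 with fish oil. Sds, Asl, Hal, Gls2, Ass1, Arg1, Cps1 and Otc are also members of the periportal list. The amino acid pattern is therefore not separate evidence from the lower periportal genes.

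The amino acid genes may be lower as a class, but without the 3 leading genes the list of 40 had adjusted p = 0.14 with an estimated correlation in limma's camera (median -0.19, 3e-08 with the preset one). One chow array may decide the pattern: the median was -0.12 without the second chow array and -0.31 without the first (SE up to 0.13). A shift from periportal to pericentral zones may also lower them, but 7 pericentral genes outside the list had a median of 0.05 (SE 0.25). Each value lies within its spread of what its explanation needs or, for the class, misses the threshold without excluding it, so these explanations cannot be told apart. Other differences in composition between chow and the high-fat diets were not tested and cannot be told apart from them either.

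Fatty acid synthesis genes were higher on the second chow array than on the first for 21 of 21 genes (median 1.57 on the log2 scale), with Fasn at 1096.8 and 105.8. Within the other diets the medians were -0.06 for lard, 0.66 for olive oil, -0.53 for coconut fat and 0.81 for fish oil. Array scaling did not account for it: 35 oxidative phosphorylation and hepatocyte genes had a median difference of 0.19 (SE 0.05 over genes). The log2 ratios of the 3' to the 5' probe set on the first and the second chow array were -0.06 and -0.04 for Gapdh and 1.151 and 1.105 for Actb. These values show no clear difference in RNA quality but do not exclude one for single transcripts. A less fasted state of the second chow sample might explain it, and genes raised by fasting had a median of -0.21 (18 genes, 11 below 0, SE 0.39), from Bcl6 (-4.06) and Igfbp1 (-3.19) to Ppargc1a (0.75) and Fgf21 (1.32), with Pck1 (-0.06), Pdk4 (0.12) and Cpt1a (0.01) near 0, a spread too wide to decide, so this cannot be told apart from other differences between the 2 samples. No biological explanation from the design applies within 1 diet.

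Of the 30 lists, 10 were called in no comparison. Their lowest limma camera adjusted p was 0.11 for the cell cycle, 0.175 for the circadian clock and for immediate early genes, 0.489 for insulin signalling, 0.361 for hepatocytes, 0.178 for endothelial cells, 0.638 for stellate cells, 0.346 for neutrophils and 0.167 for bile duct cells and adipocytes. The neutrophil and adipocyte lists had 1 gene tested each and the bile duct list 3, so their tests say little about these cell types.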
